A study of Mus musculus with 6 samples.

How the data were processed

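RNA sequencing libraries of mouse monocytes were compared between 2 groups of 3 libraries. All libraries came from mice with nephrotoxic nephritis, a model of antibody-driven glomerular injury, killed on day 13. Per the labels, 10 mice aged 8 to 10 weeks were used in the series, and kidney monocytes were enriched with a commercial isolation kit and sorted. The labels do not describe how the spleen and marrow cells were isolated. Kidney samples are named double_pos and spleen and marrow samples double, and the markers are not named. One group came from kidney (replicates 7, 8 and 22) and the other from spleen and bone marrow (replicates 2, 24 and 26). Per the labels' protocols, full-length cDNA was made with SMART-Seq v4 reagents from 2 ng of RNA, sheared to about 150 bp and turned into ThruPLEX libraries. This chemistry does not mark strand, so reads from a gene and an overlapping antisense gene cannot be told apart.

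The deposited counts are whole-number raw counts per gene symbol, with 24047 gene rows. The deposited FPKM values, scaled for depth and transcript length, were made by the authors and cover 24043 rows, of which 23983 symbols are shared with the counts. Per the submitters' processing notes, bcl2fastq 2.18, STAR 2.5, Cufflinks 2.2.1 and the mouse build mm9 were used, with no role given to each. The program that counted reads and the annotation are not given in the sources used here. Of the count rows, 22452 carry a current symbol of the GRCm38 RefSeq table and 1339 more carry a synonym in it. That table served for names only, and no coordinates are given because the builds differ. A spreadsheet had turned 27 symbols into dates. The 92 spike-in rows held no count. A microRNA row, Mir6236, took 17.1% to 17.8% of the FPKM sum in the spleen and marrow libraries and 6.96% to 9.82% in the kidney libraries, but under 1% of the counts in every library, so FPKM values were used only as an alternative.

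Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 10626, and libraries were scaled with TMM. Quasi-likelihood F tests (glmQLFit and glmQLFTest, two-sided) compared kidney with spleen and marrow, and Benjamini-Hochberg adjusted p-values under 0.05 counted as calls. The standard error of a log2 fold change is its size divided by the square root of F. CPM values are counts scaled by the TMM-adjusted library size. Against a group with no count, a fold is a lower bound computed from 3 counts over that group. With 1 to 3 counts in the group, a ratio is given with its 95% exact binomial interval. It divides each group's pooled counts by its pooled TMM-adjusted library size, kidney over spleen and marrow. Intervals and floors cover counting error only, since the reads carry no molecular identifiers.

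Before the data were examined, 38 gene lists were fixed, with 698 entries, of which 697 had a row. The 32 lists with at least 5 tested members were tested with camera (limma 3.58.1) at a preset correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Fry tests a list on its own, while camera sets it against the other genes. Named genes were also fixed by rule. The rule takes, per direction, the 12 largest log2 fold changes among calls with a mean log2 CPM of at least 4 and groups that do not overlap, leaving out unnamed loci, small RNA genes and immunoglobulin or T cell receptor segments. It adds 19 genes of monocyte biology and sex, and up to 3 called members of each list per direction by smallest p, or the 2 most abundant members of a list with no call. Of the genes the rule took, 3 are not reported here, 1 of them among the 12 largest rises. Genes outside the rule are said to have been chosen after their values were seen.

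Total counts were 8925781, 7311991 and 9727489 in spleen and marrow replicates 2, 24 and 26, and 7938223, 7824387 and 3492391 in kidney replicates 7, 8 and 22. A floor of 3 counts corresponds to between 0.322 and 0.881 CPM in a library. Data were simulated from the depths and mean levels of these libraries, with a spread set by abundance alone and 200 of 10626 genes changed. On them edgeR recovered 14.3% of 2-fold, 80.8% of 4-fold and 95.8% of 8-fold changes, with 8 false calls. No simulated library stood apart from its group, as kidney replicate 22 does, and the spread was not set per gene.

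Alternatives were DESeq2 1.42.0 and its size factors, scaling by library size, other filters, limma-voom, a test against a log2 fold of 1, a threshold of 0.01, limma-trend on log2(FPKM + 1) or log2(FPKM + 0.1), a robust fit, leaving out each replicate, and leaving out genes of the other cell type lists. Added after seeing the data were a sum of spleen and marrow replicates 24 and 26, thinning to equal depth, and sample weights. Replicate numbers are not shared between the groups, so nothing pairs the libraries. Figures were drawn with matplotlib 3.10.9.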

Results

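Gene expression was measured by RNA sequencing in monocytes from mice with nephrotoxic nephritis, 3 libraries from kidney and 3 from spleen and bone marrow. The labels call the kidney samples double_pos and the others double, without naming markers, and describe sorting for the kidney cells. The title of the series concerns the passage of monocytes to macrophage-like cells in inflamed vessels through CCR2 and endothelial TNFR2. The comparison asks how monocytes of the inflamed kidney differ from those of the sites that make and store them. No library came from healthy mice, so a difference cannot be tied to inflammation rather than to tissue. Isolation is described for kidney only, so effects of tissue and of handling cannot be told apart. The labels do not say whether the replicates are separate animals or pools, so p-values measure only the spread between these samples. Totals ran from 3492391 counts in kidney replicate 22 to 9727489 in spleen and marrow replicate 26.

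The kidney libraries carried macrophage, complement, chemokine and antigen presentation transcripts at higher levels. They carried transcripts of the cell cycle and of classical monocytes at lower levels. Which cells in the samples made these transcripts was not tested. The list calls of antigen presentation (adjusted p = 0.145), the cell cycle (adjusted p = 0.0588) and classical monocytes (adjusted p = 0.0588) were lost in camera with an estimated correlation. With that correlation 10 lists passed, and 6, 2 and 1 passed without kidney replicate 7, 8 or 22 and 2, 1 and 3 without spleen and marrow replicate 2, 24 or 26. Fry passed 21 lists. It kept the calls of antigen presentation, the cell cycle and classical monocytes (fry adjusted p = 0.0139, 0.0025 and 0.0025). Of 10626 genes tested with edgeR, 832 were higher and 627 were lower in kidney, and 736 and 403 of these differed at least 2-fold. The counts depend on the libraries. Without spleen and marrow replicate 2, 24 or 26 they were 289 and 207, 286 and 208, and 260 and 179, while without kidney replicate 22 they were 1569 and 1215. On log2(FPKM + 1) with limma-trend, 38.4% of calls were higher in kidney (407 against 654 lower), compared with 57.0% in the count test, and limma-voom gave 46.8% (737 against 838).

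The spleen and marrow libraries lay close together, with Pearson correlations of log2 CPM across genes from 0.982 to 0.990. Kidney replicates 7 and 8 correlated at 0.938 and kidney replicate 22 with them at 0.840 and 0.838, where genes are not independent replicates. Spleen and marrow replicates 24 and 26 differed by more than sampling noise, with a chi-square of 2.96 per degree of freedom, but by far less than the other within-group pairs (23.7 to 65.3). This does not show whether they are separate samples or preparations of 1 sample. They were counted as 2, and the calls depend on it, since summing them into 1 library left 299 genes higher and 201 lower.

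**Figure D1:**
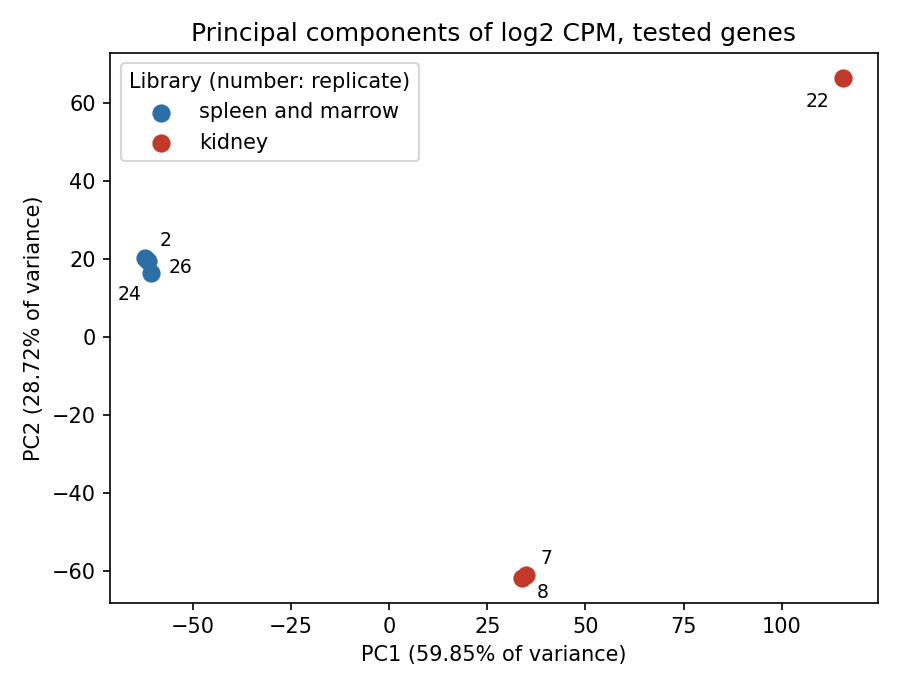
Principal components of log2 CPM over the tested genes, 1 point per library, with PC1 (59.85% of variance) on the horizontal and PC2 (28.72%) on the vertical axis in arbitrary units. The 3 spleen and marrow libraries sit together at PC1 values from -62.05 to -60.7, and kidney replicate 22 (115.46) sits apart from kidney replicates 7 (34.86) and 8 (33.86).

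Macrophage transcripts showed the clearest difference. Of 15 tested resident tissue macrophage markers, 13 rose in kidney over all genes and 13 adjusted over the list alone. C1qa and C1qc, subunits of the complement starter C1q, rose from 2.70 ± 0.459 to 790 ± 102 CPM and from 8.07 ± 2.11 to 1433 ± 140 CPM (mean ± SD, n = 3 each). Their log2 fold changes were 8.18 ± 0.22 and 7.47 ± 0.24 (SE), with edgeR adjusted p of 3.73e-06 and 9.85e-06. The list passed camera with adjusted p = 8.37e-41, and adjusted p = 0.00408 with an estimated correlation (at most 0.0371 on leaving out any 1 library). Pf4, a chemokine also abundant in platelets, rose by a log2 fold of 6.34 ± 0.26. Of 19 macrophage core markers 13 rose (14 adjusted over the list alone) and 1 fell. Axl, a receptor for apoptotic cells, rose by a log2 fold of 5.12 ± 0.42, and the growth factor receptor Csf1r by 1.67 ± 0.20. Cd14, a co-receptor for bacterial lipopolysaccharide, rose by 1.59 ± 0.16, while the lectin Lgals3 fell by 0.83 on the log2 scale. Mertk, another receptor for apoptotic cells, had 3 counts in spleen and marrow and 292 in kidney, a ratio of 125 (95% interval 42.3 to 609). The core list passed camera with adjusted p = 8.66e-13, and adjusted p = 0.014 with an estimated correlation. The latter was 0.0684 and 0.0565 without kidney replicate 22 or 8 and 0.0528 and 0.0541 without spleen and marrow replicate 2 or 24. Kidney libraries also carried more of the spleen red pulp macrophage markers, of which 4 of 8 rose (5 adjusted over the list alone), among them Axl (camera adjusted p = 5.41e-06, adjusted p = 0.0329 with an estimated correlation, and between 0.0627 and 0.112 on leaving out any 1 library). Of these 8, 2, 2 and 1 rose without spleen and marrow replicate 2, 24 or 26.

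Markers that part the blood monocyte subsets moved in opposite directions. Of 16 classical monocyte markers 7 fell and 1 rose (9 and 2 adjusted over the list alone), with camera adjusted p = 4.66e-07, but adjusted p = 0.0588 with an estimated correlation. Ly6c2, which encodes a form of the Ly6C surface protein, dropped from 5412 ± 423 to 627 ± 270 CPM (mean ± SD, n = 3 each), a log2 fold change of -3.11 ± 0.34 (SE, edgeR adjusted p = 0.00149). The detoxifying enzyme gene Mgst1 fell by 1.40 on the log2 scale. Ly6c1 was the member that rose, at 24.5, 1008 and 46.7 CPM in kidney replicates 7, 8 and 22 against 3.66 ± 0.401 in spleen and marrow. Endothelial markers summed to 39.2, 1179 and 41.4 CPM in the same kidney libraries. Ly6c1 and Ly6c2 are close in sequence, and the value of Ly6c1 is uncertain. It had a log2 fold change of -1.80 on the FPKM scale, its adjusted p with limma-voom was 0.229, and its edgeR adjusted p reached 0.133 without spleen and marrow replicate 2 and stayed above 0.05 without replicate 24 or 26. Of 16 non-classical monocyte markers 8 rose (10 adjusted over the list alone), with camera adjusted p = 4.61e-08, and adjusted p = 0.0329 with an estimated correlation. Leaving out any 1 library but kidney replicate 7 took the latter to between 0.0604 and 0.131. Leaving out spleen and marrow replicate 2, 24 or 26 left 5 that rose each time, and 1 fell without kidney replicate 22. The fractalkine receptor gene Cx3cr1 rose by a log2 fold of 2.45 ± 0.21, the Fc receptor gene Fcgr4 by 2.32 ± 0.22 and Bcl2a1d, of a family of near-identical survival genes, by 3.85 ± 0.45. The sum of the non-classical list was 1102, 2573 and 1445 CPM in kidney replicates 7, 8 and 22 against 465 ± 45.4 in spleen and marrow. Like the endothelial sum it was highest in replicate 8, whereas Cx3cr1, Fcgr4 and Bcl2a1d were highest in replicate 22.

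**Figure D2:**
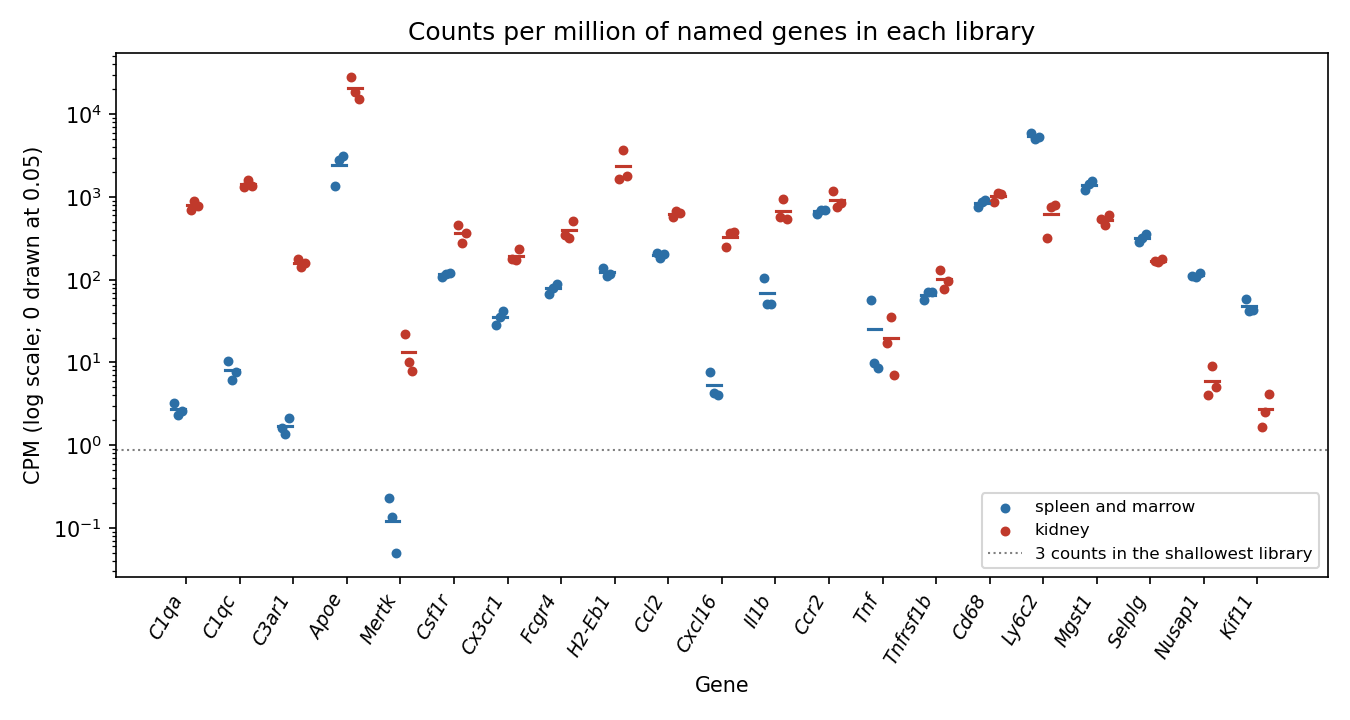
CPM of a selection of the named genes on a log axis, with 1 point per library, bars at the group means of 3 libraries and a dotted line at 3 counts in the shallowest library (0.881 CPM). C1qa runs from 2.33 to 3.22 CPM in the spleen and marrow libraries and from 700 to 901 CPM in the kidney libraries, while Ly6c2 runs the other way and Tnf overlaps between the groups.

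The genes for the receptors in the title of the series did not pass the test. Ccr2, the receptor that draws monocytes out of marrow, stood at 923 ± 216 CPM in kidney and 675 ± 45.2 CPM in spleen and marrow (mean ± SD, n = 3 each), a log2 fold change of 0.45 ± 0.18 (SE) with edgeR adjusted p = 0.141. Tnfrsf1b, which encodes TNFR2, had a log2 fold change of 0.62 ± 0.23 (edgeR adjusted p = 0.115, and 0.0478 without kidney replicate 8). These are levels in the monocyte samples, and endothelium was not measured on its own. Tnfrsf1a stood at -0.10 ± 0.15 (edgeR adjusted p = 0.705) and Tnf at -0.31 ± 0.81 (edgeR adjusted p = 0.843), where spleen and marrow replicate 2 held 56.7 CPM against 9.85 and 8.57 in replicates 24 and 26. Without replicate 2 the Tnf log2 fold change was 1.11. Cd68 (0.26 ± 0.14) and Nr4a1 (0.91 ± 0.29) also missed the edgeR threshold, with adjusted p of 0.272 and 0.0802. Nr4a1 passed without kidney replicate 22, at adjusted p = 0.00188 in edgeR, and with DESeq2 at adjusted p = 0.0331. The integrin gene Itgax rose by a log2 fold of 3.29 ± 0.46 and Emr1, which encodes F4/80, by 0.98 ± 0.14. Itgam, which encodes CD11b, rose by 1.25 ± 0.31, but its edgeR adjusted p was up to 0.159 without any 1 spleen and marrow library or without kidney replicate 7, and 0.112 with limma-trend on FPKM. The Y-linked gene Ddx3y rose from 19.2 ± 1.07 to 38.6 ± 7.89 CPM, a call lost without any 1 spleen and marrow library (edgeR adjusted p up to 0.143), after thinning (0.0716) and with limma-trend on FPKM (0.0612), and Xist had 2 counts in all libraries together.

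Of 20 chemokine genes 14 rose (15 adjusted over the list alone), with camera adjusted p = 9.83e-19, and adjusted p = 0.0427 with an estimated correlation. The latter was between 0.0604 and 0.131 on leaving out any 1 library but kidney replicate 7. Cxcl16 rose from 5.30 ± 1.98 to 331 ± 72.7 CPM and Ccl2, a ligand of CCR2, from 200 ± 14.3 to 629 ± 56.7 CPM (mean ± SD, n = 3 each). Cxcl14 had 1 count in spleen and marrow and 393 in kidney, a ratio of 504 (95% interval 90.0 to 19965). Of 14 MHC class II presentation genes 9 rose (10 adjusted over the list alone), with camera adjusted p = 1.6e-11, but adjusted p = 0.145 with an estimated correlation, and 1 fell without kidney replicate 8. H2-Eb1 and Cd74, parts of the class II complex, rose by log2 folds of 4.29 ± 0.34 and 3.52 ± 0.35, and the co-stimulator Cd86 by 1.69 ± 0.16. Kidney replicate 8, which also held the most endothelial transcripts, had 9335 CPM of Cd74 against 4141 and 4972 in replicates 7 and 22. Of 17 complement and coagulation genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with camera adjusted p = 1.16e-16, and adjusted p = 0.0124 with an estimated correlation (0.0684 without kidney replicate 22 and 0.0518 without spleen and marrow replicate 24). The receptor gene C3ar1 rose by a log2 fold of 6.52 ± 0.24. The 3 that fell were F10, F5 and C3, and their calls were lost without any 1 spleen and marrow library (edgeR adjusted p up to 0.12, 0.14 and 0.122), for F5 and C3 also without kidney replicate 7 and for C3 without kidney replicate 8.

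Genes of lipid handling, lysosomes, repair and matrix followed. Of 21 lipid handling genes 12 rose (14 adjusted over the list alone), among them Apoe, which encodes an apolipoprotein, at 20742 ± 6839 against 2424 ± 938 CPM (mean ± SD, n = 3 each), and the lipase gene Lpl with a log2 fold of 2.77 ± 0.27. This list passed camera with adjusted p = 1.68e-09, and adjusted p = 0.0329 with an estimated correlation. Of 25 lysosome genes 11 rose (13 adjusted over the list alone), with camera adjusted p = 5e-06, but adjusted p = 0.0588 with an estimated correlation. The protease gene Lgmn rose by a log2 fold of 3.12 ± 0.21. Of 16 alternative activation and repair genes 9 rose (9 adjusted over the list alone), with camera adjusted p = 1.48e-06, and adjusted p = 0.0329 with an estimated correlation. Arg1, which breaks down arginine, had 2 counts in spleen and marrow and 4317 in kidney, and Mrc1, the mannose receptor, rose by a log2 fold of 4.46 ± 0.45. The sum of the repair list was not higher in kidney, at 6795 ± 2311 against 9170 ± 4049 CPM. Its members Chil3, Chil4, Clec10a and Mgl2 had log2 fold changes of -0.65, -0.97, -0.94 and -0.36, without a call. Of 21 matrix and fibrosis genes 11 rose and 2 fell (11 and 2 adjusted over the list alone), with camera adjusted p = 3.99e-06, and adjusted p = 0.0329 with an estimated correlation. Spp1, which encodes osteopontin, stood at 1917, 1794 and 7777 CPM in kidney replicates 7, 8 and 22 against 43.4 ± 34.4 in spleen and marrow, and tubule markers summed to 1759, 1007 and 3717 CPM in the same kidney libraries. Sparc, also of this list, stood at 40.2, 1176 and 29.7 CPM, beside a sum of 74.5, 1430 and 55.5 CPM for fibroblast and mural markers, a list that shares it. Of 12 Fc receptor genes 5 rose (7 adjusted over the list alone), with camera adjusted p = 2.15e-05, and adjusted p = 0.048 with an estimated correlation. Of 22 TNF receptor and NF-kB target genes 5 rose (5 adjusted over the list alone), with camera adjusted p = 0.000362, but adjusted p = 0.29 with an estimated correlation. Of 25 immediate early and heat shock genes 5 rose (6 adjusted over the list alone), with camera adjusted p = 0.00587, but adjusted p = 0.558 with an estimated correlation and 0.326 by camera without kidney replicate 8. The numbers that rose depend on single libraries. Without spleen and marrow replicate 2, 24 or 26, they were 5, 5 and 5 for lysosome, 6, 5 and 5 for matrix (with 1 that fell without 24 or 26) and 3, 2 and 2 for immediate early genes. They were 4 and 5 for repair genes without replicate 2 or 26, 2 and 1 for NF-kB targets without replicate 24 or 26, and 7 for lipid genes without replicate 26. Without kidney replicate 22, 12 immediate early and heat shock genes rose and 2 lipid genes fell, and without kidney replicate 8, 2 immediate early genes fell. With an estimated correlation, the adjusted p of the repair, matrix and Fc receptor lists was above 0.05 on leaving out any 1 library (up to 0.0901, 0.0901 and 0.161), and that of the lipid list on leaving out any but kidney replicate 7 (up to 0.116).

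Cell cycle genes were lower in kidney as a block. Of 32 tested, 27 fell (31 adjusted over the list alone), with camera adjusted p = 1.02e-33, but adjusted p = 0.0588 with an estimated correlation. Leaving out spleen and marrow replicate 2 left 18 of the 32. Nusap1 and Kif11, which act at the mitotic spindle, fell from 114 ± 7.50 to 6.04 ± 2.69 CPM and from 48.2 ± 9.43 to 2.77 ± 1.24 CPM (mean ± SD, n = 3 each). The checkpoint kinase gene Bub1 had a log2 fold change of -4.98 ± 0.48 (edgeR adjusted p = 0.00109). The cell cycle sum was 249, 564 and 814 CPM in kidney replicates 7, 8 and 22 against 3639 ± 308 in spleen and marrow. The granule precursor sum was 303, 1267 and 14478 CPM against 9870 ± 802. In replicate 22, Camp and Ngp gave 5261 and 8146 CPM of that sum. There Elane, Mpo and Ms4a3 stood at 245, 37.3 and 62.0 CPM, against 1322 ± 353, 271 ± 75.2 and 267 ± 129 in spleen and marrow. These genes were chosen after their values were seen. Prtn3, a protease of early granulocytes, fell from 822 ± 303 to 59.5 ± 42.9 CPM. Of 12 granule precursor markers 2 fell (5 adjusted over the list alone), with camera adjusted p = 0.00117, but adjusted p = 0.324 with an estimated correlation. Of 27 oxidative phosphorylation genes 2 fell (with no call when adjusted over the list alone), at camera adjusted p = 0.00951 but adjusted p = 0.558 with an estimated correlation and 0.0785 by camera without kidney replicate 7. Of granule precursor markers, 10 fell and 2 rose without kidney replicate 22 and 1 fell without kidney replicate 8 or any 1 spleen and marrow library. Of oxidative phosphorylation genes, 5 fell without kidney replicate 22 and 1 without kidney replicate 8, and both calls were lost without kidney replicate 7 or any 1 spleen and marrow library. Of 31 ribosomal protein genes edgeR called 0, over all genes or over the list alone, with 9 lower at an unadjusted p under 0.05, 5 lower by DESeq2 and 1 by limma-voom. Their camera adjusted p was 0.00927, but adjusted p = 0.582 with an estimated correlation, and up to 0.063 by camera without kidney replicate 8 or spleen and marrow replicate 2. Without kidney replicate 22, 1 ribosomal protein gene fell.

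**Figure D3:**
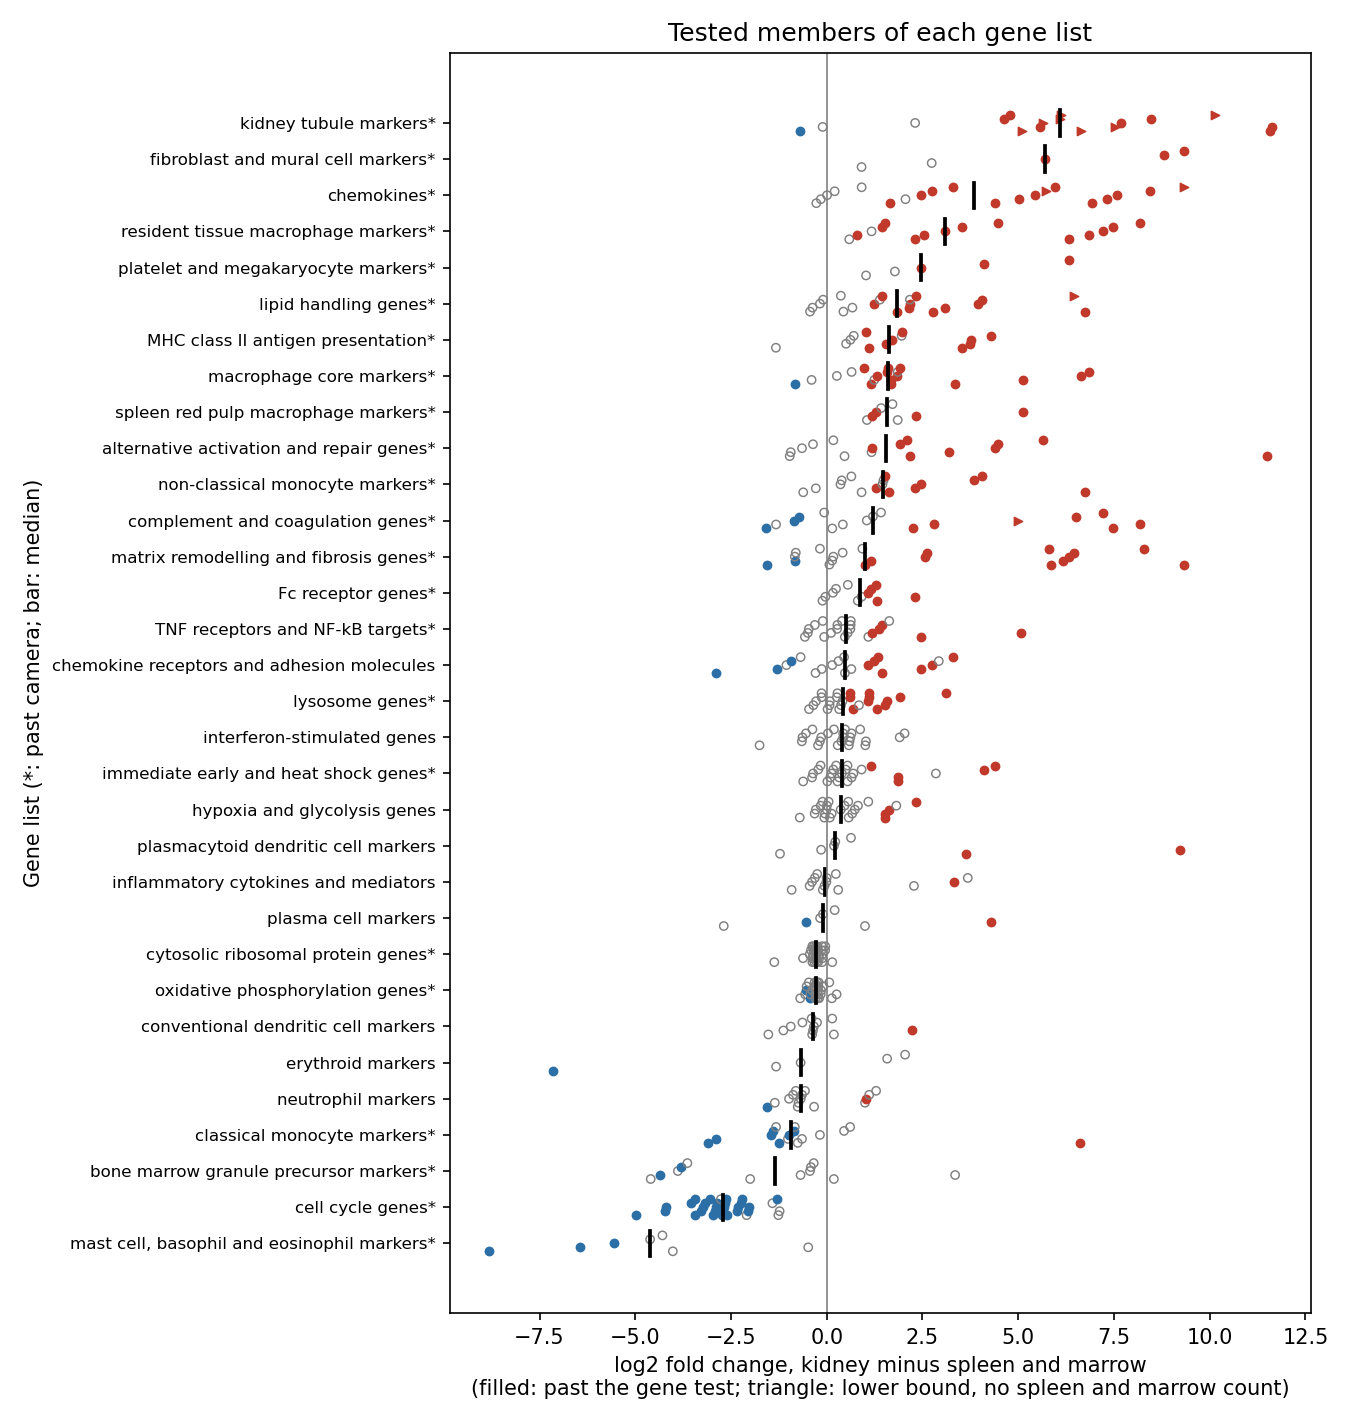
Log2 fold changes (kidney minus spleen and marrow) of the tested members of 32 gene lists, with filled points past the edgeR test, triangles at lower bounds for genes with no spleen and marrow count, and a black bar at each list's median. Of the lists, 17 passed camera as higher and 6 as lower in kidney, and 10 passed with an estimated correlation.

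The 12 largest rises and falls among well-measured genes had different make-ups. The rises include Kap and Fxyd2 of the tubule list and Ramp2 of the endothelial list. Kap, Fxyd2, Spink3, Guca2b, Tmem27, Wfdc2, Akr1c21 and Sult1d1 were highest in kidney replicate 22 and lowest in replicate 8. The tubule sum had this order, at 1759, 1007 and 3717 CPM in replicates 7, 8 and 22. Ramp2 and Cxcl13 were highest in replicate 8, and Arg1 in replicate 22. Whether monocytes made these transcripts is not settled here. Spink3, Guca2b, Tmem27, Wfdc2, Akr1c21, Sult1d1, Ramp2 and the B cell chemokine gene Cxcl13 had no spleen and marrow count, with bounds of at least 906-, 437-, 406-, 352-, 343-, 293-, 579- and 641-fold. Kap had 1 count there, Fxyd2 had 3 and Arg1 had 2, with ratios of 3477 (95% interval 623 to 137375), 2785 (953 to 13510) and 2769 (766 to 22874). The calls of Akr1c21, Ramp2 and Sult1d1 were lost without any 1 spleen and marrow library (edgeR adjusted p up to 0.0681, 0.118 and 0.063), and that of Cxcl13 without replicate 2 (0.0548). With limma-voom these 4 calls were lost (adjusted p from 0.0638 to 0.213), as were those of Spink3, Wfdc2, Kap and Fxyd2 (adjusted p of 0.0537, 0.0725, 0.0969 and 0.0692). The falls were Mcpt8, Shcbp1, Ctsg, Cst7, Nusap1, Kif11, Arhgef39, Fbxo5, Dlgap5, Prtn3, Cenpm and Fam64a, with log2 fold changes from -5.55 ± 0.99 for the basophil protease gene Mcpt8 to -3.56 ± 0.83 for Fam64a. The calls of Mcpt8, Ctsg and Fam64a were lost without any 1 spleen and marrow library (edgeR adjusted p up to 0.0638, 0.17 and 0.118), and also without kidney replicate 8 for Ctsg and replicate 7 for Fam64a. That of Ctsg was also lost with DESeq2 size factors or a stricter filter in edgeR (adjusted p of 0.0516 and 0.0518).

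Transcripts of other cell types differed between libraries. Of 17 kidney tubule markers 14 rose and 1, Napsa, fell (15 and 1 adjusted over the list alone), with a median log2 fold change of 8.48, or 6.09 with genes at 0 set to their bound (camera adjusted p = 1.38e-16, but adjusted p = 0.0588 with an estimated correlation). Without spleen and marrow replicate 2 or 26, 8 and 9 of the tubule markers rose, and the call of Napsa was lost without replicate 24 or 26 (edgeR adjusted p up to 0.0927). Their summed level was 1759, 1007 and 3717 CPM in kidney replicates 7, 8 and 22 against 881 ± 86.5 in spleen and marrow, where most of the sum was Napsa (852 ± 85.8). Endothelial markers, too few for a list test, summed to 39.2, 1179 and 41.4 CPM in kidney replicates 7, 8 and 22 against 10.2 ± 2.58. Of the 4 tested, 2 rose (4 adjusted over the list alone), 1 rose without kidney replicate 8, and both calls were lost without any 1 spleen and marrow library. In those 3 settings 10 members could be tested and edgeR called 0, with 8 higher at an unadjusted p under 0.05 each time (camera adjusted p up to 0.00211, but adjusted p from 0.506 to 0.529 with an estimated correlation). More members could also be tested without kidney replicate 22, where 9 of 9 rose (camera adjusted p = 0.000477, but adjusted p = 0.423 with an estimated correlation), and without kidney replicate 7, where 4 of 5 rose (camera adjusted p = 0.00103, but adjusted p = 0.369 with an estimated correlation). Fibroblast and mural markers stood at 74.5, 1430 and 55.5 CPM, and 3 of 5 rose (4 adjusted over the list alone), with camera adjusted p = 0.00927 but adjusted p = 0.421 with an estimated correlation. Neutrophil markers summed to 1560 and 3882 CPM in kidney replicates 7 and 8 but 33014 CPM in replicate 22, against 22541 ± 2356 in spleen and marrow. Of 15 tested, 1 rose and 1 fell (1 and 1 adjusted over the list alone), with camera adjusted p = 0.124. The list passed camera as lower without kidney replicate 22 (adjusted p = 6.43e-06, with 7 lower) and without spleen and marrow replicate 2 (adjusted p = 0.0301), but adjusted p = 0.161 and 0.462 with an estimated correlation. The rise, of Trem1, was lost without kidney replicate 7 or any 1 spleen and marrow library (edgeR adjusted p up to 0.127), and the fall, of Mmp8, without spleen and marrow replicate 24 or 26 (up to 0.0562), while 2 fell without kidney replicate 7. Of 7 mast cell, basophil and eosinophil markers 3 fell (5 adjusted over the list alone), with camera adjusted p = 5.01e-05 but adjusted p = 0.29 with an estimated correlation. Of 5 platelet markers 3 rose (3 adjusted over the list alone), with camera adjusted p = 2.7e-06 but adjusted p = 0.0588 with an estimated correlation, and Pf4 made up 327 of their 384 CPM in kidney and 4.05 of 14.3 CPM in spleen and marrow. Leaving out any 1 spleen and marrow library left 1 platelet marker that rose and ended the calls of the fibroblast and mural markers. Without kidney replicate 22, 5 platelet markers rose and 7 mast cell, basophil and eosinophil markers fell, and without kidney replicate 7, 5 fibroblast and mural markers rose.

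**Figure D4:**
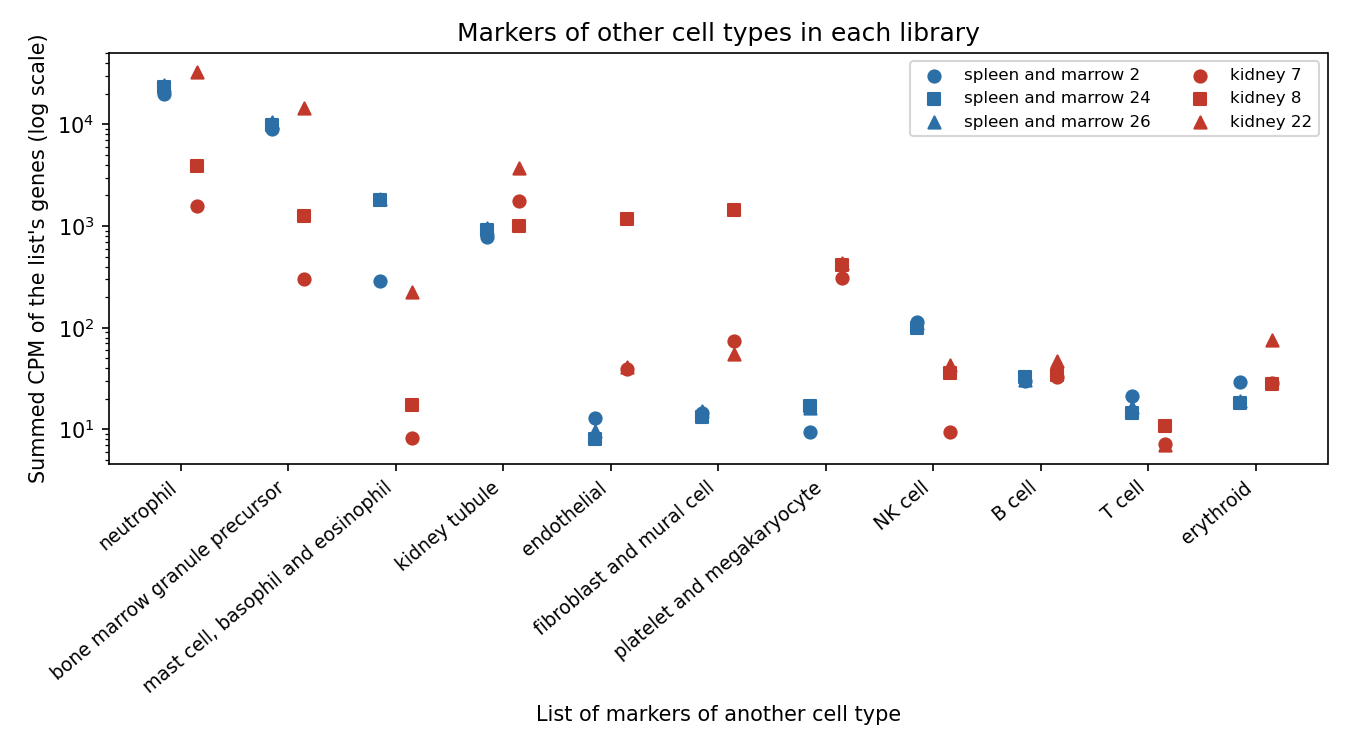
Summed CPM of marker lists of other cell types on a log axis, with 1 point per library. Kidney replicate 8 stands apart for endothelial (1179 CPM) and fibroblast and mural markers (1430 CPM), and kidney replicate 22 for neutrophil (33014 CPM) and tubule markers (3717 CPM).

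The remaining lists did not pass camera. By fry, the chemokine receptor and adhesion list (adjusted p = 0.0436) and the plasmacytoid dendritic cell list (adjusted p = 0.0325) passed. Of 24 interferon-stimulated genes edgeR called 0, over all genes or over the list alone, with 4 higher and 1 lower at an unadjusted p under 0.05, 2 higher and 1 lower by DESeq2 and 1 lower by limma-voom (camera adjusted p = 0.613). Without kidney replicate 7, 2 rose, and without kidney replicate 8, 1 rose and 2 fell. Of 14 inflammatory cytokine and mediator genes 1 rose (1 adjusted over the list alone), the cytokine gene Il1b, with a log2 fold of 3.32 ± 0.36. That list had camera adjusted p = 0.409, and 0.0106 without spleen and marrow replicate 2 (adjusted p = 0.436 with an estimated correlation), with a median log2 fold change of -0.03 but a mean of 0.52. Without spleen and marrow replicate 2 or any 1 kidney library, 2 of its genes rose. Of 20 chemokine receptor and adhesion genes 7 rose and 3 fell (7 and 4 adjusted over the list alone), with camera adjusted p = 0.191. Without spleen and marrow replicate 2, 24 or 26, 4, 2 and 2 of these rose, and without kidney replicate 22, 5 fell. Of 25 hypoxia and glycolysis genes 4 rose (4 adjusted over the list alone), with camera adjusted p = 0.101, and 0.0326 without kidney replicate 8 (adjusted p = 0.397 with an estimated correlation). Without spleen and marrow replicate 2, 24 or 26, 2, 1 and 1 rose, and without kidney replicate 22, 8 rose and 3 fell. Conventional dendritic cell (1 of 12 rose), plasmacytoid dendritic cell (2 of 7 rose, Klk1 and Atp1b1, which kidney tubules also express), plasma cell (1 of 7 rose and 1 fell) and erythroid markers (1 of 5 fell) had camera adjusted p of 0.427, 0.229, 0.692 and 0.378. Adjusted over the list alone, these counts were the same except for erythroid markers, of which 1 rose and 1 fell. The calls of Atp1b1, of the plasma cell genes Sdc1 and Xbp1 and of the erythroid gene Car1 were lost without any 1 spleen and marrow library (edgeR adjusted p up to 0.157, 0.144, 0.138 and 0.118), and that of Xbp1 also without kidney replicate 7 or 8. Without kidney replicate 8, 1 erythroid marker rose, and without kidney replicate 22, 2 plasma cell markers and 1 conventional dendritic cell marker fell. Lists with under 5 tested members were not tested, and their sums in kidney and in spleen and marrow were 38.0 ± 8.07 and 31.3 ± 1.59 CPM for B cells, 8.38 ± 2.16 and 17.5 ± 3.58 for T cells, 29.5 ± 17.7 and 108 ± 7.79 for NK cells, 303 ± 86.5 and 124 ± 14.5 for podocytes, and 107 ± 12.7 and 88.3 ± 10.5 for sex-linked genes (mean ± SD, n = 3 each). Plasma cell markers had a median log2 fold change of -0.10 but a mean of 0.28.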

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

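Summing spleen and marrow replicates 24 and 26, thinning and sample weights were chosen after the data were seen, and the cause of each change below was not tested unless stated. Against 832 genes higher and 627 lower in kidney, DESeq2 called 1438 and 1028 and limma-voom with sample weights 1352 and 1048. A test against a log2 fold of 1 gave 372 and 146, and an adjusted p threshold of 0.01 gave 322 and 189, both stricter by construction. Summing spleen and marrow replicates 24 and 26 gave 299 and 201, with fewer samples. On the FPKM scale limma-trend called 407 higher with either pseudocount and 333 with no filter. Leaving out 1 replicate gave 260 to 1569 higher and 179 to 1215 lower. Thinning every library to equal depth left 686 and 506. The gene lists that differ numbered 23, and 10 with an estimated correlation, and the other list settings gave 21 to 25 at the preset correlation. Fry passed 21 lists, 19 of them among the 23. Immediate early, oxidative phosphorylation, ribosomal protein, and fibroblast and mural lists did not pass fry (adjusted p = 0.166, 0.0935, 0.126 and 0.126). With an estimated correlation, leaving out 1 replicate gave 1 to 6 lists, summing replicates 24 and 26 gave 1 and the stricter filter 7. The median log2 fold change of all tested genes was 0.05 with TMM, 0.03 with DESeq2 size factors, 0.11 with library size and -0.16 on the FPKM scale.

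The named genes here include some chosen after their values were seen. Of 110 that were called, 67 kept the call in every setting that tested them gene by gene and 43 lost it in at least 1. The test against a log2 fold of 1, the threshold of 0.01, the robust fit, the fit without other cell type genes, sample weights and the other FPKM settings were counted over all genes only, and the FPKM setting used held 100 of the 110. Among called genes the sign changed on the FPKM scale for Ly6c1 (-1.80) and for Lyz2 (4.18), where FPKM lists Lyz2 at 0 in spleen and marrow replicate 26 alone. Among genes not called, Tnf was 0.15 with limma-voom and ran from -1.05 to 1.11 on leaving out 1 replicate, and Bst2 was -0.0019 on the FPKM scale, -0.0475 without kidney replicate 8 and at most 0.40 on leaving out another. Camp ran from -3.66 to 0.15, Ngp from -3.16 to 0.24 and Ltf from -3.35 to 0.18, with the lowest values without kidney replicate 22. Lyz2, Camp, Ngp and Ltf were chosen after their values were seen. No paired analysis was possible because the groups share no replicate number. At this depth and a spread set by abundance alone, 14.3% of simulated 2-fold changes were recovered, and the part of depth in this was not tested. The simulation held no library that stood apart as kidney replicate 22 does.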

Other observations

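The tests of a single tubule source, of carry-over from spleen and marrow and of a granulocyte precursor source were chosen only after the result was seen. Genes in this part were chosen after their values were seen unless they belong to the fixed lists. Outside those lists, Ms4a7, a membrane protein gene of macrophages, stood at 251 ± 62.7 CPM in kidney and 19.4 ± 3.78 in spleen and marrow (mean ± SD, n = 3 each), and the proteoglycan gene Sdc4 at 67.5 ± 19.6 and 1.42 ± 0.683 CPM. Within spleen and marrow, the eosinophil granule gene Prg2 stood at 163 CPM in replicate 2 and at 1478 and 1504 CPM in replicates 24 and 26. The protease gene Elane stood at 1727, 1078 and 1162 CPM in the same libraries. In kidney, the endothelial genes Emcn and Egfl7 stood at 371 and 274 CPM in replicate 8, against 6.75 and 8.77 in replicate 7 and 1.17 and 7.93 in replicate 22.

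Tubule transcripts were present in every kidney library, with Fxyd2 at 345, 123 and 773 CPM and Gpx3 at 445, 204 and 1288 CPM in replicates 7, 8 and 22. Transcription by the sorted monocytes as part of the kidney programme stays open. The tubule markers' median log2 spread between kidney libraries, 2.37, lay at percentile 100 of 10000 matched random lists of genes higher in kidney. The median of those lists was 0.92. All matched genes had been called higher in kidney, which favours a low spread, and fold change was not matched, so this cannot decide. A single outside source of tubule RNA or cells stays open: 17 of 20 markers were higher in replicate 22 than in 7 and 14 of 20 lower in replicate 8 than in 7, and the lower share, 70%, falls between the 65% and 80% set as bounds. Monocyte enrichment and sorting would be meant to remove tubule cells, and at least 1 listed gene is not tubule-specific here, Napsa at 852 CPM in spleen and marrow.

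Kidney replicate 22 stood apart from replicates 7 and 8, with S100a8 at 16137 CPM against 531 and 1682. Lower depth does not account for this, since after thinning to equal totals replicates 7 and 8 correlated by 0.0893 more than replicate 22 did with either. Carry-over from the 3 spleen and marrow libraries sequenced here is argued against by 10 of 31 neutrophil and granule genes, which were higher in replicate 22 than in the highest spleen and marrow library by a 95% counting interval, among them Camp at 5261 against 2959 CPM; for 8 of the 10 kidney replicates 7 and 8 lay below that library, as the test needs, and Trem1 and Stfa2l1 do not count. For a batch shared by the higher replicate numbers, the deviations of replicate 22 and of replicates 24 and 26 were compared. Their correlation across genes was -0.0214, where genes are not independent replicates. This argues against a batch that set replicate 22 apart through the same genes in both tissues. A smaller batch effect, or one on different genes in each tissue, stays open. No biological explanation was tested. Neutrophils or their RNA in kidney replicate 22 stay open, although monocyte enrichment and sorting would be meant to remove these cells.

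Cell cycle genes were lower in kidney. Lower depth or library scaling is argued against, since 27 of 32 still fell after thinning and 27 with library-size scaling. Granulocyte precursors in spleen and marrow as the whole source cannot be told apart from cycling monocytes there. The precursor genes Elane, Mpo, Prtn3, Ctsg and Ms4a3 had a median log2 ratio of replicate 2 over 24 and 26 of 0.85 and the cell cycle genes 0.35, a gap of 0.508 that sets 1 library against 2. The tissue difference itself stays open as untested.

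The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. For genes higher and genes lower in kidney, 1 of the 10 splits, the real one, reached 832 and 627, and the highest other split gave 0 by edgeR, where up to 236 genes had an unadjusted p under 0.05. Every other split mixes both tissues, so its gene counts are no measure of chance. For gene lists that differ, 1 of the 10 splits reached the real 23, and the other splits gave from 11 to 18. Camera at the preset correlation thus called lists in every split. The other splits keep part of the tissue difference, so their list counts are no measure of chance either. How many lists would be called without a tissue difference is not known.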
